A study of Mus musculus with 12 samples.

How the data were processed

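Expression was measured in neurospheres, floating clusters grown in culture from neural stem and progenitor cells, from the brain and the gut of newborn mice (postnatal day 0), either lacking the Polycomb gene Bmi1 or wild type. RNA of each of the 4 groups was hybridised to 3 Affymetrix mouse arrays (A, B and C) with different probe sets, which gives 12 columns of values. Array A was identified by elimination, because the labels name the other two alone. Per the labels, each column is an average that the authors took over 2 or 3 experiments: 3 for the brain knockout and 2 for the brain wild type on array A, 2 and 3 on arrays B and C, and 2 for both gut groups on all arrays. Per the labels, the labelled RNA came from 1 round of amplification for brain and 2 rounds for gut.

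The deposited values are intensity on a linear scale, given as whole numbers. Of these, 7.78% to 18.1% in a column lie below 0, so some signal had been subtracted beforehand. The kind of subtraction is not stated in the sources used here. Within a tissue, the knockout and wild type columns have nearly the same 50th, 75th, 90th and 99th percentiles, with a largest difference of 1.17% in brain and 4.30% in gut, so they were already scaled together. The software, the scale and whether values were averaged before or after scaling are not stated in the sources used here. Each group has 1 value per probe set and no spread, so no test between groups was run and no p-value, standard deviation or n is given.

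The values of each array were scaled so that the 2% trimmed means of its 4 columns were equal (factors 0.826 to 1.27). They were then set to a floor at the 40th percentile of the pooled scaled values, 187 on array A, 144 on array B and 64.5 on array C, and log2 ratios were taken. Between 58.1% and 61.7% of a column's probe sets lay above the floor. A probe set counted as differing when the ratio was 2-fold or more and at least 1 of the values was above the floor. Where the other value was at the floor, the ratio is a bound and is written "at least". Bacterial and yeast controls here are the Dap, Lys, Phe, Thr, Trpn and yeast probe sets, without the BioB, BioC, BioDn and CreX spikes. Those spikes lay above the floor on all arrays. The scaled bacterial and yeast controls reached 111 on array A, 221 on array B and 178 on array C. On arrays B and C the floor therefore lies under the brightest of these controls.

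The arrays hold 36899 probe sets, of which 198 are controls. Platform annotation gives 29131 probe sets 1 gene symbol and 724 several, and 6846 are unnamed here. Symbols were checked through their gene identifiers against RefSeq genes of assembly GRCm38.p6, where 29044 matched and 0 changed. That annotation was used for names and for the order of genes on chromosomes alone. A gene (15964 in all) is represented by the probe set with the highest mean scaled value over the 4 columns.

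Gene lists were fixed for 22 groups: Polycomb group, CDK inhibitors, p53 targets, Hox genes, S phase, G2 and M phase, neural stem and progenitor, neuron, astrocyte, oligodendrocyte, neural crest and enteric, smooth muscle, fibroblast and matrix, gut epithelium, blood and macrophage, endothelium, skeletal muscle, Hedgehog and Notch, immediate early and heat shock, antioxidant, interferon response, and cytosolic ribosomal proteins. A list is described by the median log2 ratio of its measured members and the percentile of that median among 10000 random lists of the same size, matched on mean level in 20 bins. The percentile describes these columns and is not a test across animals. The 25 measured genes on each side of Bmi1 were treated as a further list. The overlap of the brain and gut differences was set beside the number for independent lists and beside 1000 shuffles among probe sets of like signal.

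Named genes follow a rule. Bmi1 and Cdkn2a are always named. For each comparison the rule takes the 10 highest and the 10 lowest ratios among genes with both values above the floor and the higher above the 60th percentile. For the overlap it adds 10 genes in each direction and, with the same signal limits in both tissues, ranks them by the smaller of their ratios. It also adds up to 6 genes that differ in opposite directions under the same limits, and up to 4 members of each list at 2-fold or more. Other genes are named as chosen after their values were seen. Some named genes were read by probe sets with shared probes or relaxed design rules, which is not marked at each. Among them are Kif20a, Hoxc9, Hoxb4, Prph, Atf3 and Sox3. The groups, comparisons, lists, naming rule and most alternatives were fixed before the data were examined. Alternatives covered the scaling, the floor, the 2-fold threshold, the probe sets used and the choice of probe set for a gene. A floor at the brightest bacterial or yeast control and a restriction to probe sets with both values above the floor were added after seeing the data.

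The steps were tested on simulated data. For brain, 0 of 67 probe sets simulated at 1.5-fold were counted as 2-fold, against 67 of 67 at 3-fold and 66 of 66 at 4-fold. For gut, 1 of 21897 unchanged probe sets was counted, 94 of 100 lists of unchanged genes lay inside the central 95 percent of matched lists, and 50 of 50 lists shifted by 0.5 on the log2 scale were found. The simulated noise was a standard deviation of 0.13 on the log2 scale plus an additive term of 20, and holds no variation between animals. In the data, probe sets of a gene varied by more than 0.13, with standard deviations of 0.32 in brain and 0.40 in gut. The simulated counts therefore describe the steps under that noise alone and do not give error rates for the measured differences or lists. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.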

Results

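Neurospheres from the brain and the gut of newborn Bmi1 knockout and wild type mice were profiled on 3 arrays with 36899 probe sets in all. Each of the 4 groups has 1 value per probe set, the authors' mean over 2 or 3 experiments, so no difference here has a replicate check and the number of arrays limits the precision. As a handle on measurement error, the log2 ratio of a given control probe set was compared between the 3 arrays. Its standard deviation between arrays was 0.11 in brain (26 probe sets) and 0.13 in gut (23 probe sets). This covers the repeat on another array alone, and the mean ratios of different controls lay further apart. They reached -1.03 (Pcx 5') and 0.48 (MURINE_b1) in brain, and -1.35 (Gapdh 5') and 0.97 (a BioB spike) in gut. Different probe sets of a gene varied more, by 0.32 in brain over 4217 genes and by 0.40 in gut over 3942 genes. Among them, the brightest probe set was 2-fold or more for 53 genes in brain and 203 in gut. The second brightest had the same direction for 39 and 161 of these, and was 2-fold in that direction for 7 and 64. Knockout and wild type columns correlated across probe sets at 0.974 to 0.987 in brain and at 0.955 to 0.973 in gut.

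The first question was how Bmi1 itself read in each group. Bmi1, a subunit of Polycomb repressive complex 1, was lower in both knockouts. Its probe set, on array A, had a scaled intensity of 3977 in brain knockout and 6159 in brain wild type, a ratio of 0.646. In gut it read 5466 in the knockout and 8613 in the wild type, a ratio of 0.635. The targeted allele and the position of this probe set relative to the deleted part are not stated in the sources used here, so the remaining signal does not measure how much functional transcript was left. Cdkn2a, which encodes the cell cycle inhibitors p16Ink4a and p19Arf and is a known target of Bmi1 repression, was higher in both knockouts. In brain it read 1605 against 465, or 3.46-fold higher. In gut it read 504 in the knockout and 128, under the floor of 187, in the wild type, so it was at least 2.70-fold higher. With a floor at the 60th percentile both gut values lie under the floor and give no ratio.

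**Figure D1:**
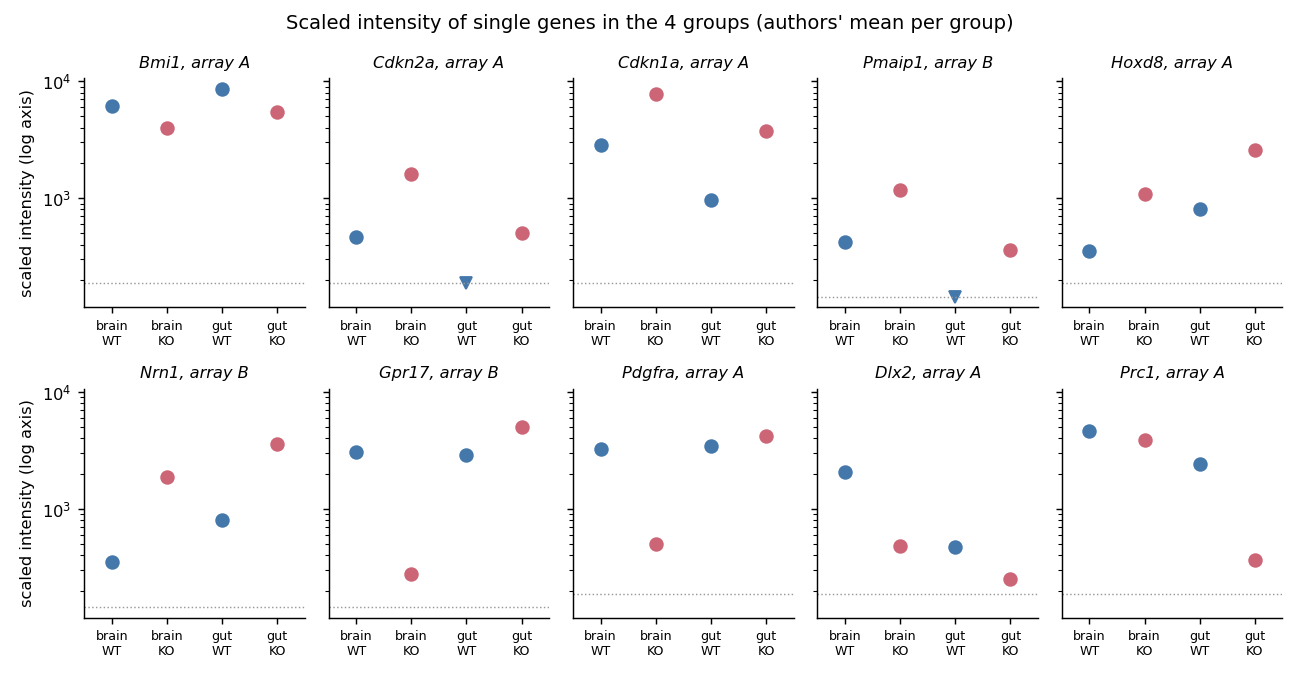
Scaled intensity (log axis) of 10 genes in brain and gut neurospheres, wild type (WT, blue) and Bmi1 knockout (KO, red), 1 point per group being the authors' mean. Dotted lines mark the floor of the array and triangles mark values at or under it; Cdkn2a, Cdkn1a, Pmaip1, Hoxd8 and Nrn1 are higher in both knockouts, while Gpr17 and Pdgfra are lower in the brain knockout and not in the gut knockout.

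In brain neurospheres, the knockout had higher levels of p53 targets and Hox genes and lower levels of genes of the oligodendrocyte lineage. Gpr17, a receptor of immature oligodendrocytes, was 11.1-fold lower (277 against 3070), and Pdgfra, the growth factor receptor of oligodendrocyte precursors, was 6.49-fold lower (496 against 3220). A second Pdgfra probe set gave a log2 ratio of -0.39. Dlx2, a transcription factor of forebrain interneuron progenitors, was 4.26-fold lower, and Dlx1 was at least 8.74-fold lower. Nrn1, which encodes the neurite growth factor neuritin, was 5.27-fold higher.

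Among 23705 probe sets compared in brain, 389 (1.64%) were 2-fold or more higher in the knockout and 335 (1.41%) lower. By gene, 190 of 12086 were higher and 114 lower. Ranked next are genes with both values above the floor and the higher above the 60th percentile. Bounds are left out, such as Hoxa5 (at least 6.06-fold) and Twist1 (at least 4.40-fold higher). Besides Nrn1 and Cdkn2a, the highest ratios belonged to the adaptor Skap2 (5.02-fold), the Groucho family corepressors Tle2 (4.38-fold) and Tle6 (3.49-fold), Sting1 (4.09-fold), the axonal scaffold ankyrin Ank3 (3.81-fold), the phosphatase Ptpro (3.36-fold), Nek3 (3.35-fold) and Cluap1 (3.35-fold). Sting1 was read by a probe set with shared probes, and its other probe set gave -0.56. Under the same limits, after Gpr17 and Pdgfra, the lowest were the ventral forebrain factor Nkx2-1 (5.72-fold lower), Retreg1 (5.36-fold), Flrt2 (4.64-fold), Bcas1 (4.45-fold), Dlx2, the neurotensin receptor Ntsr2 (4.13-fold), Pdzrn3 (4.05-fold) and Emp1 (3.82-fold). Dlx1, left out as a bound, was at least 8.74-fold lower. Nkx2-1 and Flrt2 were read by probe sets picked under relaxed design rules, and Flrt2 was under 2-fold with a floor at the 60th percentile. The lower values of Nek3, Cluap1, Nkx2-1 and Flrt2 lie under the brightest bacterial or yeast control of their array, and as bounds at that control Nek3 and Flrt2 are under 2-fold. The counts depend on the floor: with it at the 20th and at the 60th percentile, 1700 and 138 probe sets were higher and 1712 and 81 lower.

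Of 16 measured p53 targets, 3 were 2-fold or more higher in brain knockout, 0 lower and 13 within 2-fold, and 15 lay above 0. Pmaip1, a proapoptotic gene, was 2.82-fold higher, the CDK inhibitor Cdkn1a 2.69-fold and Ccng1 2.37-fold. The list median, 0.50, lay above those of all 10000 matched lists. Of 18 Hox genes, the positional identity genes that Polycomb complexes repress, 4 were higher and 0 lower: Hoxa5 at least 6.06-fold, Hoxd9 at least 3.11-fold, Hoxd8 3.09-fold and Hoxb4 2.31-fold. With a floor at the 60th percentile, Hoxa5 (0.89), Hoxd8 (0.84) and Hoxd9 (0.38) were under 2-fold, as was Hoxb4 (0.47) by the median over its probe sets. The list median of 0.37 also exceeded all matched lists. Of 14 oligodendrocyte genes, 5 were lower and 0 higher, with a median of -0.63 below all matched lists (-0.34 with the median over each gene's probe sets). Besides Gpr17, Pdgfra and Bcas1 they were Ugt8a, an enzyme of myelin lipid synthesis (3.20-fold lower), and Myrf (2.01-fold lower). Ugt8a was under 2-fold with a floor at the brightest bacterial or yeast control (-0.69) and by the median over its probe sets (-0.49). Myrf, chosen after its value was seen, was under 2-fold with a floor at the 60th percentile and with a pseudocount. In the same list 5 members had log2 ratios above 0 and 9 below. Those above 0, chosen after their values were seen, were Olig1 (0.30), Cspg4 (0.43), Nkx2-2 (0.59), Mbp (0.40) and Mag (0.02). The 3' to 5' intensity ratio of the control transcript Pcx differed between the brain columns, with a mean of 5.99 in the knockout and 3.13 in the wild type.

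Genes of cell division differed little in brain. None of 28 S phase genes reached 2-fold (median -0.09, percentile 6.93). None of 29 G2 and M phase genes did so either, but 24 of them lay below 0 and the median of -0.24 was below all matched lists. Of 7 CDK inhibitors, Cdkn2a and Cdkn1a were higher and 5 were within 2-fold, with a median of -0.28 (percentile 1.01), so the list median and its 2 differing members had opposite signs. Of 25 neural stem and progenitor genes 24 were within 2-fold, the exception being Id4 (2.74-fold lower), with a median of -0.04. Of 20 neuronal genes, Dlx1, Dlx2 and Dcx, a marker of young neurons (2.29-fold lower), were lower and 17 within 2-fold, with a median of -0.01. Of 20 astrocyte genes, Gjb6 was 2.34-fold lower and 19 were within 2-fold (median 0.12, percentile 97.49, and 0.044 by the median over a gene's probe sets). In the neural crest and enteric list (16 genes, median 0.23, percentile 99.7, between 0.068 and 0.40 under other settings), Twist1 was at least 4.40-fold and Tfap2a 2.54-fold higher. In the smooth muscle list (11 genes, median 0.33, percentile 99.7, and 0.18 by the median over a gene's probe sets), Itga8 was 2.72-fold higher. Itga8 is among the 50 genes nearest to Bmi1, so alleles linked to the targeted locus stay open for it. Thy1 (2.89-fold) and Sparc (2.24-fold) were higher in the fibroblast and matrix list of 14 (median -0.06).

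The remaining lists held few 2-fold differences in brain. All 18 antioxidant genes (median 0.21, percentile 99.7), all 20 ribosomal protein genes (median -0.14, percentile 0.45) and all 20 Polycomb group genes (median -0.04) were within 2-fold. Jag1, a Notch ligand, was 2.75-fold higher (log2 ratio 0.42 by the median over its probe sets) among 17 Hedgehog and Notch genes (median 0.01), and Tap1 2.06-fold higher among 10 interferon response genes (median 0.06). Medians were -0.02 for 17 immediate early and heat shock genes, -0.15 for 7 gut epithelium genes, 0.02 for 6 blood and macrophage genes, -0.05 for 4 endothelial genes and 0.08 for 7 skeletal muscle genes, with 0 members at 2-fold in any of them. The 50 genes nearest to Bmi1 had a median of -0.09 (percentile 3.14), with 3 higher and 2 lower. Among all genes 1.57% were higher and 0.94% lower, so 2-fold differences were more frequent among these 50. Of the genes named for brain, Dcx, Gjb6, Mdga2, Mfng, Nek3, Pcp4l1, Tap1, Twist1 and Ugt8a were also under 2-fold with a floor at the 60th percentile, Hoxd9, Mdga2, Slc16a9 and Sting1 by the median over a gene's probe sets, Gjb6 and Mdga2 with a floor at the brightest control, and Csrp1, Dcx, Gjb6, Mfng, Sparc and Tap1 with a pseudocount.

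**Figure D2:**
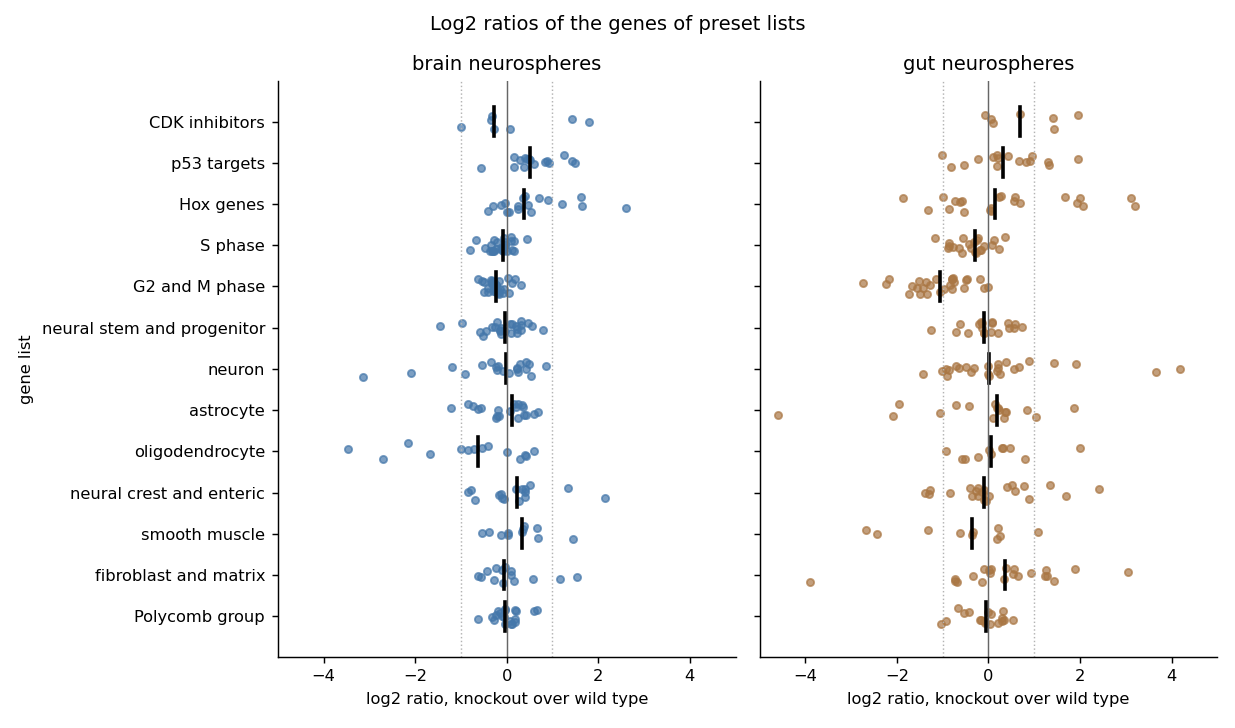
Log2 ratio of knockout over wild type for each measured gene of 13 preset lists in brain (blue) and gut (brown) neurospheres; thick bars are list medians and dotted lines mark 2-fold. Oligodendrocyte genes have a median of -0.63 in brain and 0.05 in gut, G2 and M phase genes -0.24 in brain and -1.06 in gut.

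In gut neurospheres, the knockout had lower levels of mitotic genes and higher levels of CDK inhibitors and of several Hox genes. Prc1, a protein of the mitotic spindle midzone, was 6.68-fold lower (364 against 2431), and Ect2, which directs cytokinesis, was 6.87-fold lower. Hoxc6 was 9.24-fold higher (4000 against 433). Rxfp3, a relaxin family peptide receptor, read 5555 against 165; the lower value is under the brightest bacterial or yeast control of its array (178), which makes it at least 31.1-fold higher as a bound at that control.

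Among 22812 probe sets compared in gut, 667 (2.92%) were 2-fold or more higher in the knockout and 735 (3.22%) lower. By gene, 401 of 11942 were higher and 392 lower. Ranked next are genes with both values above the floor and the higher above the 60th percentile. Bounds are left out, such as Nefl (at least 18.3-fold) and Gad1 (at least 12.7-fold higher). Under these limits the highest, after Rxfp3 and with Hoxc6, were Lrtm1 (10.03-fold), the neuropeptide Adcyap1 (7.83-fold), Opcml (7.72-fold), the caveolar protein Cav1 (7.52-fold), the axon repellent Sema3a (7.39-fold), the retinoic acid enzyme Aldh1a1 (6.81-fold), Col13a1 (6.70-fold) and the somatostatin receptor Sstr2 (6.44-fold). The lower values of Opcml and Sema3a also lie just under the brightest control of their array (221). Under the same limits the lowest were Apoe (24.1-fold lower), Gpr101 (23.5-fold), Gch1, the first enzyme of tetrahydrobiopterin synthesis (11.0-fold), the noncoding RNA Miat (9.52-fold), Gas2l3 (7.52-fold), the neuropeptide galanin, Gal (6.94-fold), Ect2, Dio2 (6.85-fold), Prc1 and Myl9 (6.39-fold). Ccn2, left out as a bound, was at least 14.9-fold lower. A second probe set of Apoe gave a log2 ratio of 0.15, so its probe sets disagreed. With a floor at the 20th and at the 60th percentile, 2011 and 347 probe sets were higher and 2101 and 352 lower.

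Of 27 measured G2 and M phase genes in gut, 14 were 2-fold or more lower in the knockout, 13 within 2-fold and 0 higher, and all 27 lay below 0. Besides Prc1, Kif20a was at least 4.73-fold lower, the proliferation marker Mki67 at least 4.51-fold and Ccnb2 3.33-fold. The list median of -1.06 was below all matched lists, and with a floor at the 60th percentile it was -0.50. Of 22 S phase genes, Rrm1 was 2.25-fold lower and 21 within 2-fold (median -0.30, percentile 0.42, and -0.63 with a floor at the 20th percentile). Of 7 CDK inhibitors, Cdkn1a (3.90-fold), Cdkn2a and Cdkn1c (2.67-fold) were higher (median 0.69, percentile 99.9, and 0.40 with a floor at the 60th percentile). Of 16 p53 targets, Cdkn1a, Pmaip1 (at least 2.52-fold) and Sesn2 (2.47-fold) were higher and Sesn1 was 2.03-fold lower (median 0.32, percentile 99.5, and 0.49 by the median over a gene's probe sets). Beside these groups, signs of RNA quality differed between the gut columns: the mean 3' to 5' intensity ratio of Gapdh was 9.90 in the knockout and 5.52 in the wild type, and that of Actb was 8.66 and 4.76. That of Pcx was 2.01 and 1.22, but for its 3' and its 5' probe set 1 gut value did not exceed the floor on at least 1 array. In brain the Gapdh and Actb ratios lay between 0.905 and 1.20.

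**Figure D3:**
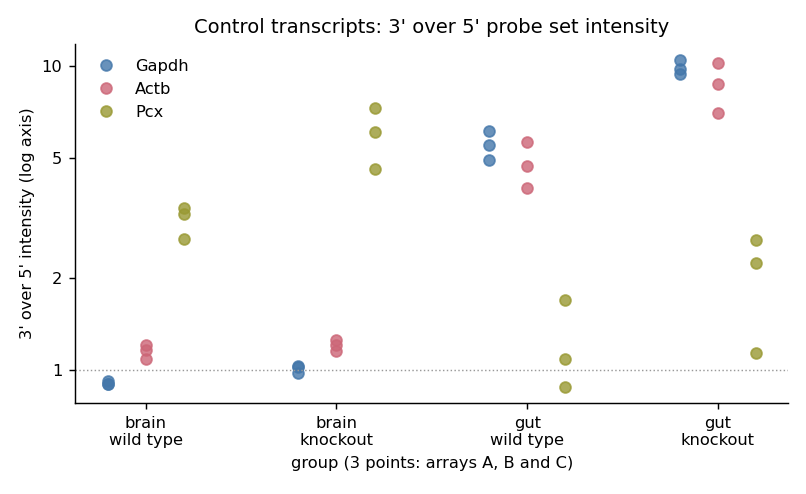
Ratio of 3' to 5' probe set intensity (log axis) of the control transcripts Gapdh, Actb and Pcx in the 4 groups, with 1 point for each of the 3 arrays. The mean Gapdh ratio is 0.905 and 1.01 in brain wild type and knockout, and 5.52 and 9.90 in gut wild type and knockout; the mean Pcx ratio is 3.13 and 5.99 in brain wild type and knockout.

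Of 22 Hox genes in gut, 6 were higher and 2 lower in the knockout, with a median of 0.14 (percentile 85.0, and 0.27 with a floor at the 60th percentile). The higher ones included Hoxc6, Hoxc9 (at least 8.67-fold), Hoxd9 (at least 4.17-fold) and Hoxc8 (3.99-fold). Of 10 smooth muscle genes, Myl9, Tagln (at least 5.38-fold) and Acta2 (2.504-fold) were lower, and Mylk was 2.11-fold higher (median -0.35, percentile 2.09). When the floor is at the 60th percentile, both values of Acta2 lie under it, Tagln was -0.72 and the list median -0.080. Of 22 fibroblast and matrix genes, 6 were higher and 1 lower (median 0.37, percentile 99.98): Thy1 was at least 8.21-fold, Fbln2 3.72-fold and Col1a1 2.70-fold higher, and Ccn2, a connective tissue growth factor, at least 14.9-fold lower. Of 25 neuronal genes, 4 were higher and 2 lower (median 0.01), with Nefl at least 18.3-fold, Gad1 at least 12.7-fold, Prph 3.78-fold and Rbfox3 2.71-fold higher. The lower ones were Dlx1 (at least 2.70-fold), as in brain, and Syt1 (2.03-fold), both named for gut after their values were seen. Both gut values of Dlx1 lie under a floor at the 60th percentile, and Syt1 was under 2-fold with a pseudocount. Of 17 astrocyte genes, 2 were higher and 4 lower (median 0.20, percentile 97.3). Slc1a2 was 4.22-fold (log2 ratio -0.74 by the median over its probe sets) and Gfap 3.86-fold lower, and Tnc 3.64-fold higher. Of 22 neural crest and enteric genes, 3 were higher and 3 lower (median -0.10, percentile 17.3), among them Npy (5.34-fold higher), Gfra3 (3.23-fold higher), Twist1 (at least 2.54-fold higher) and the nicotinic receptor Chrna3 (2.63-fold lower).

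In the other gut lists, Cspg4 was at least 4.01-fold higher among 11 oligodendrocyte genes (median 0.05, percentile 60.8), and Fabp7 was 2.37-fold lower among 19 neural stem and progenitor genes (median -0.10). Rnf2 was 2.05-fold lower among 18 Polycomb group genes (median -0.05). Mycn (3.61-fold), Hhip (3.21-fold) and Hey1 (2.001-fold) were lower and Notch3 was 2.02-fold higher among 15 Hedgehog and Notch genes (median -0.10). Trib3 was 4.03-fold higher and Fos 2.24-fold lower among 20 immediate early and heat shock genes (median 0.09), and Sod2 was 2.05-fold higher and Gsta4 3.11-fold lower among 17 antioxidant genes (median 0.07). Lyz2 was 2.82-fold lower among 9 blood and macrophage genes (median -0.09), and Eng was 3.33-fold higher and Kdr 4.01-fold lower among 5 endothelial genes (median 0.37, between 0.026 and 0.66 under other settings), but by the median over its probe sets Eng was 0.88, Kdr -0.65 and Sod2 0.51. Ribosomal protein genes (20, median -0.18, percentile 5.90), interferon response genes (16, median 0.03), gut epithelium genes (5, median 0.02) and skeletal muscle genes (7, median 0.16) had 0 members at 2-fold. The 50 genes nearest to Bmi1 had a median of -0.10 (percentile 6.53), with 2 higher and 1 lower, where 3.36% of all genes were higher and 3.28% lower. Of the genes named for gut, Cspg4, Hey1, Hoxd9, Kdr, Kif20a, Lyz2, Mdga2, Mfng, Mki67, Notch3, Pmaip1, Rbfox3, Rrm1, Trib3 and Twist1 were also under 2-fold with a floor at the 60th percentile, Hey1, Rbfox3 and Rrm1 by the median over a gene's probe sets, Rnf2, Sesn1 and Sod2 with quantile normalization, Hhip, Mdga2 and Pmaip1 with a floor at the brightest control, and Acta2, Hey1, Lyz2, Mfng, Notch3, Pmaip1, Rnf2, Rrm1, Sesn1, Sod2 and Twist1 with a pseudocount.

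The knockouts of both tissues were next set side by side. Nrn1, Ank3, Hoxd8, Tle6 and Cdkn1a were higher in both, and Bnip3, a mitophagy receptor that responds to low oxygen, was lower in both. Nrn1 was 5.27-fold higher in brain and 4.47-fold in gut, Ank3 3.81-fold and 4.80-fold, Pcp4l1 3.18-fold and 3.30-fold, and Hoxd8 3.09-fold and 3.19-fold. Tle6, Cpne8, Mdga2, Slc16a9, Ano3 and Cdkn1a completed the 10 genes with the largest smaller ratio among those with all 4 values above the floor and the higher value of each tissue above the 60th percentile. Hs3st2, Hoxd9, Thsd7a, Thy1 and Cdkn2a, each with at least 1 value at the floor, have a larger smaller ratio than Cdkn1a, as a bound. Bnip3 was 2.91-fold lower in brain and 2.48-fold in gut, and both of its probe sets gave negative ratios in both tissues. Csrp2, Dlx1 and Ndrg1, each with at least 1 value at the floor, have a larger smaller ratio than Bnip3, as a bound.

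Of 20706 probe sets compared in both tissues, 53 were 2-fold higher in both knockouts, where independent lists would share 7.67 and 1000 shuffles gave at most 18. Lower in both were 25, against 7.38 for independent lists and at most 17 in shuffles. In opposite directions, 16 were lower in brain and higher in gut (6.12 for independent lists, at most 15 in shuffles) and 9 higher in brain and lower in gut (9.25, at most 21), so a small excess over shuffles was not particular to shared directions. By gene, 38 were higher in both (shuffles at most 14) and 10 lower in both (shuffles at most 11), while 6 were lower in brain and higher in gut (shuffles at most 10). Across probe sets, which are not independent replicates, the log2 ratios of the tissues had a Pearson correlation of 0.1204 and a Spearman correlation of 0.112. The Pearson value was 0.269 on array A and 0.060 on arrays B and C. After Bnip3, the lower genes under the naming rule were Csrp1 (2.04-fold in brain and 2.14-fold in gut), Mfng, Plekhb1, Miat, Pdk1, Arih1, Mxi1, Cerox1 and Ttyh1, of which those after Mfng were under 2-fold in at least one tissue. Arih1 is uncertain in brain, where its log2 ratio was -1.07 by the brightest probe set and 0.03 by the median of its probe sets.

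**Figure D4:**
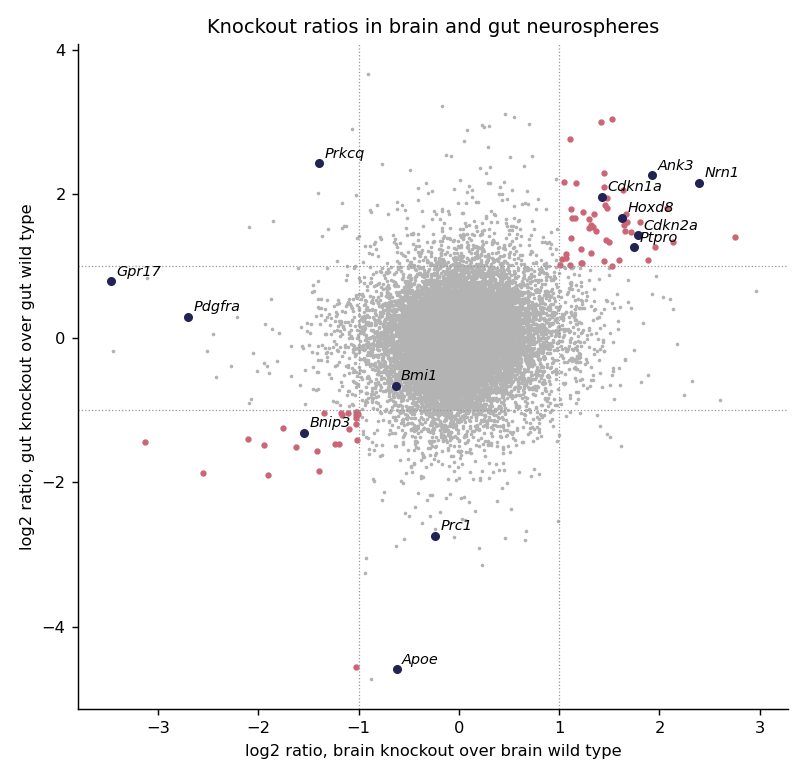
Log2 ratio of knockout over wild type in brain (horizontal) against gut (vertical) for 20706 probe sets; dotted lines mark 2-fold, red points are 2-fold in the same direction in both tissues and dark points are named genes. The upper right field holds 53 probe sets and the lower left 25.

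The wild type columns compared gut with brain neurospheres, where tissue and the number of amplification rounds (2 and 1) differ together. By list median, neural crest and enteric, neuronal, and fibroblast and matrix genes were higher in gut, and astrocyte genes and genes of cell division were higher in brain. Hand2, a transcription factor of enteric neuron development, was 88.3-fold higher in gut, and Kcna1, a neuronal potassium channel, 93.5-fold; as bounds at the brightest bacterial or yeast control, which exceeds their brain values, they are at least 83.8-fold and 49.8-fold higher. Acsbg1, an acyl-CoA synthetase of astrocytes and other brain cells, was 44.7-fold lower in gut, and the growth factor receptor Egfr 24.0-fold lower.

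Of 24651 probe sets compared, 3642 (14.8%) were higher in gut and 4296 (17.4%) lower, so that 45.9% of the differences were higher. With the deposited values unscaled, 4818 were higher and 3473 lower, or 58.1% higher, and the median ratio on array C was then 0.44 against -0.12 with scaling. Other genes with the highest ratios were Atf3 (109.0-fold), Sgpp2 (84.4-fold), Bgn (76.1-fold), Celf4 (63.6-fold), Chgb (54.4-fold), Entpd3 (51.1-fold), Matn2 (49.1-fold) and Gpr101 (47.5-fold). The lowest also included Timp4 (28.3-fold lower), Rrm2 (26.3-fold), Ptprz1 (25.9-fold), Slc4a4 (24.8-fold), Myo10 (24.0-fold), Phpt1 (23.5-fold), Lfng (22.8-fold) and Ccdc124 (20.9-fold). The lower values of Sgpp2, Bgn, Gpr101, Timp4, Slc4a4, Lfng and Ccdc124 lie under that control too, where Bgn is at least 37.3-fold and Sgpp2 at least 40.1-fold higher. By the median over its probe sets, the log2 ratio of Bgn was 2.32.

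By list, 13 of 21 neural crest and enteric genes were higher in gut and 1 lower (median 1.62), including the glial receptor Erbb3 (at least 58.8-fold) and Gfra1 (37.8-fold). Of 22 fibroblast and matrix genes, 14 were higher and 2 lower (median 2.80), with Dcn at least 127-fold and Postn at least 109-fold higher. Of 25 neuronal genes, 13 were higher and 4 lower (median 1.33, and 0.82 with a floor at the 20th percentile), with Elavl4 42.4-fold higher (at least 34.1-fold as a bound at the brightest control). Of 20 Hox genes, 14 were higher and 0 lower (median 1.46, and 0.74 with a floor at the 60th percentile), with Hoxb5 12.9-fold higher. Smooth muscle genes had a median of 0.84 (5 of 12 higher, 1 lower). Lower in gut were 21 of 28 S phase genes (median -2.004, and -1.22 with a floor at the 60th percentile, Mcm7 12.9-fold lower), 25 of 29 G2 and M phase genes (median -2.35, Cdk1 15.2-fold lower), 14 of 25 neural stem and progenitor genes (median -1.16, Sox3 19.2-fold lower) and 13 of 20 astrocyte genes (median -2.04, and -1.26 by the median over a gene's probe sets, Aldh1l1 at least 113-fold lower). Probe sets of a gene varied by a standard deviation of 0.95 in this comparison, 0.32 and 0.40 being the values within brain and gut.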

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

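In this part, the tests on values near the floor, on the share of oligodendrocyte lineage cells and on shuffled overlaps were chosen only after the result was seen. The genes below point in opposite directions in brain and gut knockouts, a difference between tissues that was not tested because each group has 1 value. The log2 ratio in brain minus that in gut was -3.83 for Prkcq, a protein kinase C isoform that was 2.63-fold lower in brain and 5.40-fold higher in gut, with a second probe set in the same directions. Prkcq is among the 50 genes nearest to Bmi1, so alleles linked to the targeted locus stay open for it. It was -3.00 for Nkain4, -2.68 for Sntg2 and -2.12 for Mfap2, all lower in brain and higher in gut. Hip1 went the other way, with a difference of 2.24. Each of these genes was under 2-fold in some setting: Prkcq and Sntg2 in brain and Mfap2 in gut with a floor at the 60th percentile, Nkain4 in brain with a pseudocount (-0.85), and, by the median over a gene's probe sets, both Hip1 (0.73 in brain and -0.68 in gut) and Sntg2 (-0.83 and 0.68).

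Control probe sets outside the comparisons also differed between the gut columns. The 5' probe sets had mean log2 ratios of knockout to wild type of -1.35 for Gapdh and -0.83 for Actb. The BioB, BioC, BioDn and CreX spike controls were higher in the knockout by 0.58. In brain the Gapdh 5' value was -0.19 and the spike value -0.06, while the Pcx 5' value was -1.03.

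The lower level of G2 and M phase genes in gut knockout was weighed against RNA yield. If the second amplification round yielded some genes poorly, random genes with like levels and like gut to brain ratios were predicted to be lower too. The list median of -1.06 had a percentile of 0 among 10000 such lists. Tissue and number of rounds differ together, so the gut to brain ratio does not measure yield alone. The percentile therefore cannot decide on this cause. Values near the floor were also weighed. With a floor at the 60th percentile all 16 members left lay below 0, with a median of -0.50, below all matched lists at that floor. Most of them passed it through the wild type value alone, which fixes their sign, so the test cannot exclude this cause for the list. Ccnb2 (-1.74), Bub3 (-1.49), Mad2l1 (-0.96) and Plk1 (-0.02) had both values above that floor, so their ratios do not rest on it. The size of the list median does depend on the floor, since -0.50 is closer to 0 than -1.06. Truncated RNA at the position of each probe set cannot be told apart from a difference in transcripts: the other probe sets of these genes had a median of -0.28, closer to 0 than the brightest ones, but only 8 probe sets could be compared and their positions are not given. A lower share of dividing cells in the gut knockout, which the genotype could bring about, stays open and untested.

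The lower level of oligodendrocyte lineage genes in brain knockout (median -0.63) was also weighed against values near the floor. The median of the 11 members left with a floor at the 60th percentile was -0.55, below all matched lists at that floor. It is the value of Mobp, whose knockout value (345) lies just above that floor (344). Gpr17, Pdgfra, Bcas1, Myrf and Ugt8a passed the floor through the wild type alone, which fixes their sign. With both values above it, Mobp, Sox10 and Olig2 lay below 0 and Olig1, Cspg4 and Nkx2-2 above. The median therefore cannot decide on values near the floor. A lower share of all cells of the lineage would place all 9 members with a mean log2 level above the 60th percentile below 0. Of them 2, Cspg4 and Nkx2-2, lay above 0 by more than the spread between probe sets (0.32). Olig1 (0.30) also lay above 0, but within that spread. The 2 are fewer than the number set for excluding this cause, and other progenitors may also express both. An effect of the genotype on the lineage stays open, as does a difference between the cultures averaged in each column. Truncated RNA at the position of each probe set was not tested for this list. In brain the mean 3' to 5' ratio of Pcx was 5.99 in the knockout and 3.13 in the wild type. Those of Gapdh and Actb lay between 0.905 and 1.20 in both columns.

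The genes higher in both knockouts exceeded chance overlap at the same signal level, with 53 probe sets against at most 18 in 1000 shuffles. Probe sets lower in brain and higher in gut also passed their shuffles, by less (16 against at most 15). Among probe sets with all 4 values above the floor, 34 remained, more than any shuffle of those probe sets gave (at most 11), which argues against values near the floor. Alleles linked to the targeted locus would place an excess on the chromosome of Bmi1, where 4 of the 38 genes lie, with 2.998 expected and an upper limit of 7, and 0 are among the 50 genes nearest to Bmi1. A shared response to the loss of Bmi1 may explain them, as a hypothesis found and examined on the same columns. Differences in handling between knockout and wild type cultures that both tissues share were not tested.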

How the results depend on the processing

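In this part, the floor at the brightest bacterial or yeast control and the restriction to both values above the floor were chosen after the result was seen. All other alternatives were planned. Each group has 1 value, so leaving out a replicate was not possible. Replicates could not be paired because the columns are means that carry no replicate numbers. The tissues were not used as pairs, and no test was run. Of 88 count results under the alternatives 53 stayed within 1.5 times the main count. Of 528 list medians 469 moved by less than the standard deviation of the medians of matched lists. Of 1888 values of named genes 1619 moved by less than the spread between probe sets of a gene. Sign changes of genes were counted only where the main value was 2-fold or more, and 2 such values changed sign. Low signal limits some results: 40 of 224 named 2-fold values fell under 2-fold with a floor at the 60th percentile, against 25 with the median over a gene's probe sets and 23 with a pseudocount. The causes of the moves below were not tested beyond what each setting does by construction: a lower floor admits dimmer probe sets, and a higher floor, 3-fold and one value per gene leave fewer.

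With a floor at the 20th percentile, counts were both tissues 290 higher and 251 lower, brain 1700 higher and 1712 lower, gut 2011 higher and 2101 lower, wild type 6811 lower. List medians there were in gut G2 and M phase -1.58, S phase -0.63, endothelium 0.66 and neuron 0.13, and in brain Hedgehog and Notch 0.10, Hox genes 0.55 and neural crest and enteric 0.068, and in the wild type comparison Hox genes 1.19, neural crest and enteric 2.09 and neuron 0.82. With a floor at the 60th percentile, counts were both tissues 24 higher and 7 lower, brain 138 higher and 81 lower, gut 347 higher and 352 lower, wild type 2499 lower. List medians there were in gut CDK inhibitors 0.40, G2 and M phase -0.50, Hox genes 0.27, endothelium 0.026, neuron 0.19 and smooth muscle -0.080, and in the wild type comparison G2 and M phase -1.74, Hox genes 0.74, S phase -1.22, gut epithelium 0.38, neural crest and enteric 2.09, p53 targets -0.28 and skeletal muscle -0.55, and in brain Hedgehog and Notch 0.10, Hox genes 0.52, Polycomb group 0.076, neural crest and enteric 0.40, neuron 0.22 and skeletal muscle -0.21. With a floor at the brightest bacterial or yeast control, counts were brain 219 higher and 192 lower. List medians there were in gut G2 and M phase -1.28 and S phase -0.46, and in brain Hedgehog and Notch 0.19, Hox genes 0.53 and neuron 0.090, and in the wild type comparison Hox genes 1.87, immediate early and heat shock 0.59 and neuron 1.66. With a pseudocount instead of a floor, counts were brain 220 lower, gut 432 lower. List medians there were in the wild type comparison G2 and M phase -1.91, S phase -1.56 and fibroblast and matrix 2.53, and in brain Hox genes 0.27, neural crest and enteric 0.14 and oligodendrocyte -0.43. At 3-fold, counts were both tissues 8 higher and 2 lower, brain 57 higher and 45 lower, gut 183 higher and 137 lower, wild type 1868 higher and 2075 lower. With one value per gene, counts were both tissues 10 lower, brain 190 higher and 114 lower, gut 401 higher and 392 lower, wild type 2022 higher and 2263 lower. With both values above the floor, counts were both tissues 34 higher and 14 lower. With the median over a gene's probe sets, list medians were in the wild type comparison G2 and M phase -1.90, Polycomb group 0.0025, S phase -1.75, astrocyte -1.26 and fibroblast and matrix 2.41, and in gut Hedgehog and Notch 0.14, neural stem and progenitor 0.073 and p53 targets 0.49, and in brain astrocyte 0.044, fibroblast and matrix 0.028, neural crest and enteric 0.080, neural stem and progenitor -0.15, neuron -0.18, oligodendrocyte -0.34 and smooth muscle 0.18. With no scaling, list medians were in the wild type comparison p53 targets -0.38.

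Cdkn2a in brain was 1.39 with a floor at the 60th percentile and 1.46 with a pseudocount. In gut it was 1.97 with a floor at the 20th percentile or at the brightest control, and 0 with a floor at the 60th percentile, where both values are at the floor; the wild type comparison of Cdkn2a was 0 there too. The correlation of brain and gut ratios was 0.0495 with a floor at the 20th percentile. With the median over a gene's probe sets, Arih1 in brain turned to 0.026 and Rpl22 in the wild type comparison to 0.47.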

Other observations

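Genes that respond to low oxygen were noticed among those lower in both knockouts: Bnip3, Ndrg1, Pdk1 and Mxi1 had log2 ratios of -1.54, -1.42, -1.53 and -0.91 in brain and of -1.31, -1.56, -0.91 and -0.89 in gut. The brain value of Ndrg1 is a bound, its knockout value being under the floor. These genes and the others named here were chosen after values were seen. A list of 26 further genes of that response, which left out genes already seen, was then written down. In brain, 21 of its 24 measured members lay below 0 and 4 were 2-fold lower, 0 higher. Among them the hexokinase Hk2 had a log2 ratio of -1.15, the angiogenic factor Vegfa -1.04, the phosphofructokinase Pfkl -1.04 and Ddit4 -1.03. In gut, 13 of 21 measured members lay below 0 and 2 were 2-fold lower, Ldha (-1.03) and Higd1a (-1.51), 0 higher.

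The tests for brain alone and gut alone were chosen only after the result was seen. The test set down beforehand asked whether a lower response to hypoxia in the knockout spheres held in both tissues, with list medians under the 2.5 percentile of matched lists in each. It failed: the higher of the percentiles was 8.85, that of gut, where the median was -0.14. Taken alone, brain had a median of -0.30 and a percentile of 0, which a lower response to hypoxia in the knockout spheres could explain. Because this split followed the failed joint test, it is a hypothesis for other samples. Sphere size and culture density, which also set oxygen levels, are not stated in the sources used here.

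In the wild type comparison, 6 of 16 interferon response genes were higher in gut than in brain and 0 lower (median 0.88), with Irf9 4.48-fold and B2m 3.08-fold higher. Ribosomal protein genes were lower in gut by list median (-0.65, percentile 0.90), with 8 of 20 at 2-fold or more and 12 within 2-fold. By the median over a gene's probe sets, Rpl22 (0.47) and Rpl10a (-0.24) were no longer 2-fold lower. The Polycomb list was mixed, with 5 of 20 higher and 3 lower (median 0.44, and 0.0025 with the median over each gene's probe sets) and Ezh1 8.60-fold higher. Of 14 oligodendrocyte genes, 6 were lower in gut (median -0.39), with Olig2 at least 30.9-fold lower.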
